A study of Homo sapiens with 47 samples.

How the data were processed

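The series holds 47 libraries from HEK293T, a human embryonic kidney cell line transformed with adenovirus DNA and SV40 large T antigen. Of these, 31 belong to R-ChIP, which maps R-loops, structures in which nascent RNA pairs with the DNA template and leaves the other DNA strand single. A V5-tagged, catalytically dead ribonuclease H1 (D210N) binds the RNA-DNA hybrids, and the bound chromatin is recovered with an anti-V5 antibody and sequenced. The labels put 20 R-ChIP libraries in the V5 groups (10 groups of 2) and 11 among the inputs, and the remaining 16 are GRO-seq libraries of nascent RNA. The V5 groups cross 5 inducible factors (wild-type SRSF2, SRSF2 P95H, wild-type U2AF35, U2AF35 S34F and U2AF35 Q157P; U2AF35 is the protein of U2AF1) with 0 or 5 h of doxycycline at 1 µg/ml. All 47 libraries were assigned to a group from their titles. The title of the U2AF35 S34F input names no doxycycline condition.

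One processed file was used, a peak list that by its name combines the R-ChIP libraries, and it holds 0 values per library. The 0 h and 5 h groups and the wild-type and mutant factors therefore could not be compared, and the comparisons planned for counts per library were not made. Signal tracks and GRO-seq values were not used here. Total reads per library are not known from the list, so no depth can be set beside a peak.

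Bowtie2, SAMtools and MACS2 and the human build hg18 are named in the submitters' processing notes, without versions. The deposited list has the MACS2 narrowPeak layout with an empty strand column, and the strand stands in each peak's name. Whether it is the strand of the transcript or of the sequenced DNA is not given in the sources used here. The fold enrichment in the deposited list is a ratio of the combined R-ChIP signal to a control at the summit. The deposited list also gives a −log10 q-value per peak and a score, which equalled 10 times −log10 q cut to a whole number, within 1, in all 14307 peaks. These per-peak values are the authors' own and serve only to describe and rank peaks within the list. The lowest fold enrichment was 5.00, the shortest peak 150 bp and the lowest −log10 q 5.96. Peak numbers ran to 11621 on the plus strand and 11742 on the minus strand, so that 61.2% of the 23363 numbers were in the list. Why the others are absent is not given in the sources used here. Any share of peaks with a neighbour therefore misses neighbours under these limits and any other peak that is not in the list.

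Peaks on the 22 autosomes, X and Y (14295) were analysed, and 12 on random contigs were set aside. Coordinates are hg18 and 1-based. No hg18 annotation or sequence was used here, so no peak was given a gene name, and the planned tests of promoters, gene lists and base composition were not run. The RefSeq gene table of GRCh38.p14 served only to count genes per chromosome, and none of its coordinates were used. The cluster histone genes counted there were protein-coding genes named H1-, H2AC, H2BC, H3C or H4C with a number.

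The share of plus-strand peaks and the arrangement of opposite-strand pairs were tested with two-sided exact binomial tests, with 95% Clopper-Pearson intervals that cover counting error only and treat peaks as independent. Differences of median fold and rank correlations were tested with 100000 permutations, two-sided. An opposite-strand neighbour was a summit on the other strand within 1000 bp, and its share was compared with 10000 permutations of the strand labels within chromosomes. Peaks of the same strand never overlapped in the list (0 were merged), so this reference puts the expected share too low. As a further reference, chosen after seeing the data, all minus-strand peaks were shifted together by 10 to 1000 kb, 1000 times. A pair was a plus-strand and a minus-strand peak that were mutually nearest within 1000 bp; the arrangement with the minus-strand summit at the lower coordinate is called divergent and the other convergent. Intervals of median fold ratios within pairs were taken from order statistics. Same-strand clustering was the share of peaks with a same-strand summit within 5000 bp, against 1000 uniform draws over each chromosome's span of peaks. Benjamini-Hochberg adjustment ran over the 8 tests. Peaks are not biological replicates, and every p-value concerns this list rather than the spread between cultures.

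The alternatives were a stricter threshold (−log10 q of 10 or more), only peaks at or above the median fold, all sequences of the list, merged same-strand peaks, distances of 500, 2000 and 10000 bp, midpoints in place of summits, overlap by 1 bp, all annotated genes, and autosomes only. They and the rule for named items were set before the data were examined: the 10 peaks of highest fold, the highest of each chromosome, the 3 widest peaks, the 3 divergent pairs with the highest weaker member, and the 5 windows of 1 Mb with the most peaks. The shifted minus-strand peaks, the split of pairs by overlap, the omission of chromosome 6 and the omission of the 3 windows with the most peaks were added after seeing the data. The statistics were tested on simulated data: in a list of 15295 simulated peaks with 1000 planted pairs, 13.1% of peaks had a planted partner and 13.6% were recovered with one, and of planted pairs 70% were divergent and 69.2% were recovered so. Simulated lone peaks had uniform positions, random strands and equal widths, and same-strand overlap was not excluded. The simulation thus checks the counting of pairs and not how the references behave on the real list. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.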

Results

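R-loops were mapped by R-ChIP in HEK293T cells with doxycycline-inducible wild-type or mutant SRSF2 or U2AF35, in 20 V5 libraries (10 with doxycycline and 10 without) and 11 inputs. SRSF2 is a serine/arginine-rich splicing factor and U2AF35 the subunit of U2AF that reads the 3′ splice site, and both are recurrently mutated in myelodysplastic syndromes. The study set out to compare R-loops with and without expression of the mutant factors. The values analysed were 14295 chromosomal peaks of a combined list, with 1 fold enrichment per peak and none per library, so differences between doxycycline conditions or between factors were not analysed here. What follows describes where the R-loop peaks lay, how strong they were and how the strands were arranged.

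The R-loop peaks were short and mostly of modest enrichment, with a small very strong group. The median peak was 258 bp wide (quartiles 188 and 367 bp) and 7.99-fold enriched over the control (quartiles 6.05 and 12.8). Below 10-fold lay 9143 peaks (64.0%), while 1720 (12.0%) reached 20-fold and 21 reached 100-fold. The peak widths summed to 4282 kb, with bases shared by overlapping peaks of opposite strands counted on each strand. Wider peaks were stronger, with a Spearman rho of 0.63 across 14295 peaks (permutation p = 1e-05, the smallest that 100000 permutations can give). Genomic positions are not independent replicates, so the rho describes this list. Width and fold both come from the signal of the same peak, so part of the relation may follow from the calling, which was not tested.

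The 10 strongest peaks lay on 7 chromosomes. Of the 200 strongest, 43 (21.5%) lay on chromosome 6, which held 7.51% of all peaks. The highest fold enrichment, 208.6, belonged to a minus-strand peak at chromosome 1 positions 8008543 to 8009108. On the short arm of chromosome 6, a minus-strand peak at 28871406 to 28871987 (148.9-fold) and a plus-strand peak at 28871425 to 28872443 (147.3-fold) overlapped, and a further minus-strand peak at 26419066 to 26419724 reached 140.2-fold. Chromosome 16 held a plus-strand peak of 148.6-fold at 70017738 to 70018432, and chromosome 7 a minus-strand peak of 139.6-fold at 148311434 to 148312022. The plus-strand peaks at chromosome 15 positions 43277813 to 43278561 and chromosome 4 positions 154606829 to 154607422 reached 130.4-fold and 126.9-fold. The minus-strand peaks at chromosome 5 positions 180581210 to 180582209 and chromosome 1 positions 202742048 to 202743018 reached 117.6-fold and 113.0-fold. These 10 peaks lay in 9 different windows of 1 Mb, and 3 of them lay in the 3 windows with the most peaks. Every autosome and X had a peak of at least 56.8-fold, the value of the highest peak on chromosome 9 (130749710 to 130750082). The highest on X reached 73.3-fold at 18602699 to 18603339. The widest peaks were on the plus strand, 1851 bp at chromosome 11 positions 59074319 to 59076169 (104.1-fold), 1780 bp at chromosome 17 positions 7962942 to 7964721 (41.4-fold) and 1669 bp at chromosome 17 positions 8030326 to 8031994 (55.2-fold). With no hg18 annotation used, these positions carry no gene names here.

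Both strands carried about as many peaks, of about the same strength. The plus strand held 7229 peaks and the minus strand 7066, a plus-strand share of 50.6% (95% exact interval 49.7 to 51.4%) that was not distinguishable from 50% (exact binomial p = 0.175, adjusted p = 0.175). Among peaks at or above the median fold, the plus-strand share was 51.2% with an exact p of 0.0444. The median fold was 8.07 on the plus strand and 7.90 on the minus strand, a difference of 0.17 that did not pass the permutation test (p = 0.0794, adjusted p = 0.0907). Among peaks at or above the median fold the difference had the other sign, −0.07 (permutation p = 0.723).

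R-loop peaks of opposite strands lay next to each other far more often than when the minus-strand peaks were shifted along the chromosomes. Of the 14295 peaks, 6286 (44.0%, exact interval 43.2 to 44.8%) had an opposite-strand summit within 1000 bp. Permuted strand labels gave a mean of 28.6% and at most 30.2% (permutation p = 0.0002, adjusted p = 0.00032, the former the smallest that 10000 two-sided permutations can give). Same-strand peaks never overlapped in the list, so permuted labels put the expected share too low. An overlapping peak on the opposite strand was present for 3566 peaks (24.9%), against 12.8% with permuted labels. Part of the excess was thus fixed in advance, and this p-value cannot by itself show pairing. With minus-strand peaks shifted along the chromosomes, a reference chosen after seeing the data, the mean was 0.88% and the highest value 1.47%. Such a shift also parts peaks that only gather in the same regions, so it does not show pairing beyond shared regions. Peaks with an opposite-strand neighbour were stronger, with a median of 9.61-fold against 7.03-fold for lone peaks (difference 2.58, permutation p = 1e-05, adjusted p = 2e-05). The share with a neighbour was 24.8% among the weakest 10% of peaks (5.00 to 5.39-fold) and 70.1% among the strongest 10% (22.2 to 208.6-fold). For an overlapping opposite-strand peak, the shares were 11.5% and 56.4%, while the median width was 181 bp in the weakest and 446 bp in the strongest 10%. Neighbours below the 5.00-fold limit, or absent from the list for another reason, are not counted.

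**Figure D1:**
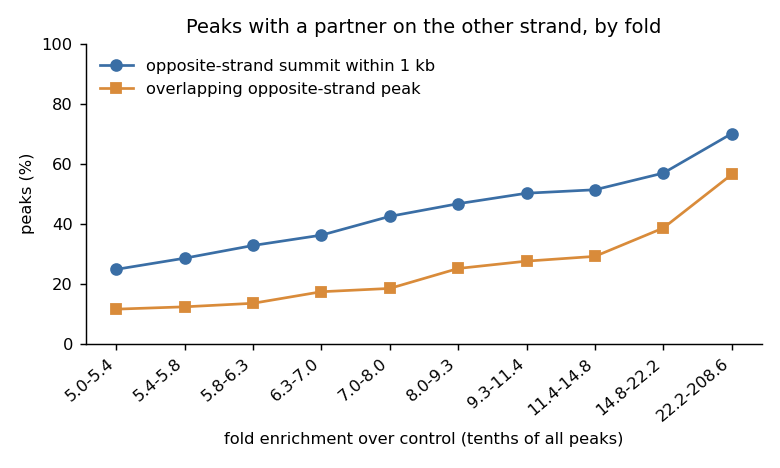
Percent of R-ChIP peaks (y axis) that have an opposite-strand summit within 1 kb (blue circles) or an overlapping opposite-strand peak (orange squares), for 10 equal parts of all 14295 peaks ordered by fold enrichment (x axis, lowest and highest fold of each part). The shares run from 24.8% to 70.1% and from 11.5% to 56.4% between the weakest and the strongest 10%.

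The nearest opposite-strand peaks fell into 2 arrangements. In 1735 of 2818 mutually nearest pairs (61.6%, exact interval 59.7 to 63.4%) the minus-strand summit lay at the lower coordinate, the divergent arrangement, which differed from 50% (exact binomial p = 7.19e-35, adjusted p = 5.75e-34). The divergent summits were a median of 324 bp apart (quartiles 213 and 443 bp), against 125 bp (quartiles 84 and 191 bp) for the 1083 convergent pairs. Where the paired peaks did not overlap, 992 of 1131 pairs (87.7%, exact interval 85.7 to 89.6%) were divergent, with summits a median of 406 bp apart (exact p = 3.21e-159). Where they overlapped, the majority turned: 743 of 1687 pairs (44.0%, exact interval 41.7 to 46.4%) were divergent and 944 convergent (exact p = 1.09e-06). The split by overlap was made after seeing the data. Overlapping pairs also have closer summits, so the split partly restates the difference of distance between divergent and convergent pairs. One further pair had equal summits and was left out of the tests. Since the list does not say whose strand it names, the 2 arrangements would exchange names if it were the complementary one.

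The divergent pairs whose weaker member was strongest lay on chromosomes 11, 8 and 14. On chromosome 11 the plus-strand peak at 59074319 to 59076169 (104.1-fold) and the minus-strand peak at 59074455 to 59076028 (109.9-fold) had summits 77 bp apart. On chromosome 8 the plus-strand peak at 124238394 to 124239175 (83.8-fold) and the minus-strand peak at 124238109 to 124238925 (94.3-fold) had summits 11 bp apart. On chromosome 14 the plus-strand peak at 20169126 to 20169537 (102.1-fold) and the minus-strand peak at 20168826 to 20169300 (77.9-fold) had summits 181 bp apart. In all 3 the peaks overlapped. Across all 2819 pairs, the stronger member had a median of 14.3-fold and the weaker a median of 7.40-fold.

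Peaks also gathered on the same strand and in a few regions. A same-strand summit lay within 5000 bp for 2987 peaks (20.9%, exact interval 20.2 to 21.6%), against a mean of 2.74% and at most 3.31% for uniform positions (p = 0.002, the smallest that 1000 random draws give in this two-sided permutation-type test, adjusted p = 0.00267). Uniform positions ignore that genes themselves cluster. The 3 fullest windows of 1 Mb were adjacent on chromosome 6, with 75 peaks in the window from 26000001 to 27000000, 101 in that from 27000001 to 28000000 and 78 in that from 28000001 to 29000000. The next were 43 peaks on chromosome 1 from 153000001 to 154000000 and 41 on chromosome 17 from 7000001 to 8000000. The median over the 2411 windows with a peak was 4.

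Chromosomes with more genes carried more R-loop peaks. Across the 22 autosomes and X, the number of peaks rose with the number of protein-coding genes, with a Pearson r of 0.90 and a Spearman rho of 0.91 (permutation p = 1e-05 for each, adjusted p of r = 2e-05). Without chromosomes 1 and 21, those farthest from the median gene number, r was 0.81 (permutation p = 3e-05). Chromosome length was not taken into account, so a relation with gene number cannot be told apart here from one with length. Chromosome 6 had the most peaks for its genes, 102.4 per 100 protein-coding genes, and the largest share of peaks of 20-fold or more, 20.02%. The lowest values among these were those of chromosome 19 with 46.4 and X with 46.8 peaks per 100 protein-coding genes. Per 100 annotated genes of any kind, chromosome 6 again had the most peaks (31.7), but the lowest values were those of chromosome 18 (16.4) and X (17.0), and chromosome 19 had 24.9. On X 4.53% of the 397 peaks reached 20-fold and 29.5% had an opposite-strand neighbour, the lowest values of the 22 autosomes and X. Of the peak numbers on X, 49.3% were in the list, against 61.2% of all numbers. Absent peaks can lower the share with a neighbour and the number per gene, and their part was not tested. The list held 0 mitochondrial peaks, with its filters not known. It placed 3 peaks on Y, of 5.38, 15.4 and 7.65-fold. Whether their reads came from Y was not tested, so they are not shown to be R-loops of Y.

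**Figure D2:**
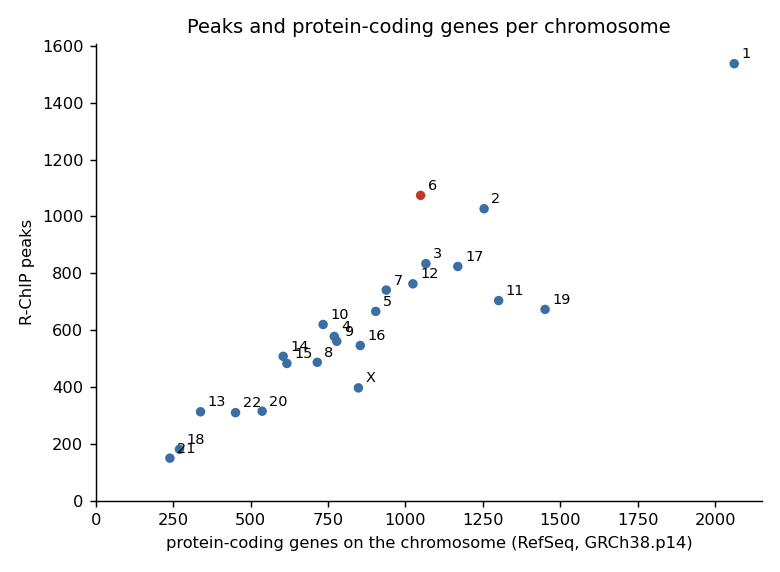
R-ChIP peaks per chromosome (y axis) against protein-coding genes per chromosome in the RefSeq table of GRCh38.p14 (x axis), 1 point for each autosome and X, with chromosome 6 in red. Chromosome 6 lies above the trend with 1074 peaks, and chromosomes 19 and X lie below it with 673 and 397.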

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

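The list held 12 peaks on random contigs, sequences that hg18 assigns to a chromosome without a position, which entered none of the comparisons in the report and only the alternative with all sequences of the list. They were picked out because a count of 12 lies above the 3 that a count of 0 allows. They comprised 5 on the contigs of chromosome 17, 4 on those of chromosome 21, and 1 each on those of chromosomes 1, 6 and X. No explanation was tested.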

How the results depend on the processing

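Of 44 alternatives over the 8 results, 4 could not come out otherwise, since same-strand peaks never overlapped in the list: merging them changed nothing in 3 results (0 overlapped), and overlap by 1 bp (24.9% of peaks, 12.8% with permuted labels) is possible only with the opposite strand. Of the other 40, 37 kept the direction and the side of the threshold of 0.05. The alternative with all sequences of the list added only 12 peaks to the 14295, so it could move each result little. The shifted minus-strand peaks, also among the 40, part peaks that only share a region, so their agreement adds little too. Among the 40 are the other alternatives of opposite-strand neighbours with permuted labels, and part of their excess was fixed in the same way. The plus-strand share became 51.2%, past the threshold, among peaks at or above the median fold, and there the strand difference of median fold turned to −0.0699, with permutation p above 0.05 before and after; the cause was not tested. The share of divergent pairs turned to 44.0% among overlapping pairs, a split added after seeing the data. Also added then, the omission of chromosome 6 gave a paired-against-lone difference of 2.44, and that of the 3 fullest windows an r of 0.92. Elsewhere the divergent share ranged up to 87.7% and was 61.9% at the stricter q, 57.9% within 500 bp and 67.0% between midpoints. Opposite-strand neighbours ranged from 37.2% (500 bp) to 45.7% (2000 bp), the median difference of paired and lone peaks from 2.15 to 2.81, the rho of width and fold from 0.48 to 0.63, same-strand clustering from 13.2% to 24.9%, and r of peaks and genes from 0.89 to 0.96. Promoter, gene-list and base-composition settings were not run, since no hg18 annotation or sequence was used here. No paired analysis was possible because the list gives no value per library, and leaving out replicates was not possible for the same reason. Depth per library is unknown, and neighbours under 5.00-fold or otherwise absent from the list are missed.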

Other observations

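The bounds of the tests of explanations were written before their results were seen; the test of fold within chromosome 6, the omission of the fullest windows of every autosome, the intervals of the fold ratios, the values of overlapping divergent pairs, and the relations of the remaining peaks and without chromosomes 1 and 14 were chosen afterwards. All patterns were found and tested on the same list.

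The peaks in the 3 fullest windows of 1 Mb, from 26 to 29 Mb of chromosome 6, were stronger than those on the rest of the chromosome. Their median fold was 18.7, against 7.76 (difference 10.9, permutation p = 1e-05), and 118 of the 254 (46.5%) reached 20-fold. The windows form a contiguous region chosen for its number of peaks. The permutation exchanged neighbouring peaks as if they were independent, so its p-value only describes this list. Chromosome 6 also held 21.5% of the 200 highest peaks of the genome, against 7.51% of all peaks. In the RefSeq table of GRCh38.p14, it holds 155 of 443 nuclear tRNA genes (34.99%), 55 of 73 cluster histone genes (75.3%) and 5.24% of protein-coding genes. tRNA genes are transcribed by RNA polymerase III, and the cluster histone genes encode the replication-dependent histones.

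Chromosome 6 carried more peaks than its gene number gives. A gain of the whole chromosome in these cells would raise calls along all of it, unless the control rose equally. Without the 3 fullest windows it had 78.2 peaks per 100 protein-coding genes, within the 46.4 to 92.6 of the other autosomes, but these windows were chosen for their peaks, only chromosome 6 lost any, and their genes were left in the count, so the bound set beforehand excludes nothing. When every autosome lost its own 3 fullest windows, the median of the others was 65.5 and only chromosome 13 (82.5) lay above chromosome 6. Chromosomes 10 and 2 lay just below it, with 76.8 each. These values do not set the rest of chromosome 6 apart from the other autosomes. They do not exclude a gain either, so a gain stays open. That tRNA genes carry peaks of high fold is a hypothesis that predicts the same link elsewhere: across the 21 other autosomes and X, the 200 highest peaks and the tRNA genes, each per 100 protein-coding genes, had a Spearman rho of 0.45 (permutation p = 0.0361, adjusted p = 0.0722 over 2 relations) and a Pearson r of 0.45 (permutation p = 0.0367), and without chromosomes 1 and 14 as well rho was 0.47 (permutation p = 0.0376) and r was 0.55 (permutation p = 0.0126), neither adjusted. For the remaining peaks rho was 0.23 (permutation p = 0.296), and the difference between the relations was not tested. The values are in line with the hypothesis but miss the adjusted threshold, and the cluster histone genes stay open, as they lie mainly on chromosome 6. Neither gene class was matched to peaks by position.

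Overlapping opposite-strand pairs were mostly convergent, with summits a median of 114.5 bp apart (quartiles 76 and 155 bp), an offset that sheared double-stranded fragments read from both ends could also give if the list names the sequenced strand, which is not known; if it names the other strand, the overlapping divergent pairs are the ones concerned. Such fragments alone would give both members about the same fold. The median ratio of the stronger to the weaker was 1.76 (95% interval 1.69 to 1.84) with a Spearman rho of the folds of 0.19 across the 944 convergent pairs, and 1.61 (1.54 to 1.68) with a rho of 0.31 across the 743 divergent pairs, so both intervals lie above the bound of 1.5, set beforehand for the convergent pairs, which argues against such fragments as the whole source under either reading. A fixed part of every strong peak copied to the other strand would give a partner to nearly all strong peaks. In the strongest 10% the share with an overlapping partner was 56.4%, between the bounds of 50% and 80% set beforehand. A fixed part would also give all pairs about the same ratio, for which no bound was set. The ratio had quartiles of 1.26 and 2.71 in the overlapping convergent pairs, and of 1.24 and 2.43 in the overlapping divergent pairs. The ratio thus varied between pairs, but the spread that a fixed part with noise would give was not computed. With the share between its bounds, these values do not decide whether a fixed part is the whole source of the pairs. A small copied part stays open too, since a copy under the 5.00-fold limit would not be listed. A copied part that varies between loci, a mixture of both sources, and R-loops on both strands also stay open, and no biological explanation was tested since no group of the design is in the list.

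The share of peak numbers present in the list differed between chromosomes, from 45.9% on chromosome 13, 49.3% on X and 51.3% on chromosome 18 to 70.5% on chromosome 17, with Y left out. The longest run of absent numbers was 16, on the minus strand of chromosome 18 between 32662737 and 41801337.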
